A study of Mus musculus with 32 samples.

How the data were processed

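RNA from early-passage primary mouse embryonic fibroblasts (MEFs) was measured on 2 Affymetrix expression array types, named array A and array B here. There were 16 RNA extracts and 32 samples, with 4 replicates in each of 4 groups: wild type unirradiated, wild type irradiated, Oct-1 mutant unirradiated and Oct-1 mutant irradiated. Oct-1 is a POU domain transcription factor encoded by Pou2f1. The replicate number of Oct-1 mutant unirradiated replicate 1 was missing from its array A label and was taken from the array B label with the same title number. The deposited values are log2 probe set values, summarised and scaled by the authors. The log base was taken from their range, 0.265 to 15.75 on array A and 0.0973 to 15.51 on array B, and the method is not given in the sources used here. Array medians lay between 6.16 and 6.28 on array A and between 3.67 and 3.78 on array B, so no further scaling was applied. Radiation dose, time after irradiation and the origin of the replicates are also not given in the sources used here. The p-values therefore describe the spread between these samples only, and 4 arrays per group limit the precision.

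Array A held 22690 probe sets and array B 22575, of which 64 on each were controls. Annotation assigned 1 gene to 20380 probe sets of array A and to 14661 of array B. Symbols were updated through gene identifiers for 20351 and 14486 of these. Control probe sets were left out of the tests, and probe sets with a mean at or above the 40th percentile were kept, which left 13582 on array A (mean of at least 4.96) and 13502 on array B (at least 3.36). The annotation named 0 probe sets for Pou2f1 itself, so the mutated gene's own level was not analysed here. Genome coordinates of probe sets are not given in the sources used here.

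Each array type was fitted separately with limma 3.58.1 in R 4.3.3, with 4 group means and moderated tests that let the variance follow intensity. Figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Comparisons were irradiation within each genotype, the difference of these effects (mutant minus wild type), genotype within each irradiation state, and both effects averaged over the other factor. P-values were adjusted by the Benjamini-Hochberg method within each array type and comparison, and a probe set was called at an adjusted p under 0.05. Counts of called probe sets are summed over both arrays, 27084 tests in all. A gene measured by several probe sets can be counted several times.

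Before the data were examined, 31 gene lists, the comparisons, the naming rule and the alternatives were fixed. The lists covered p53 targets, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones and DNA repair. Metabolic lists held NRF2 and antioxidant genes, glycolysis, oxidative phosphorylation and the TCA cycle, cholesterol synthesis and fatty acid metabolism. They also covered the interferon response, NF-kB and inflammatory mediators, immediate early genes, the unfolded protein response, heat shock, apoptosis regulators, extracellular matrix, TGF-beta targets and contractile genes, and the hypoxia response. The remaining lists held POU factors with octamer coactivators, Hox and positional genes, imprinted genes, sex-linked marker genes, and markers of macrophage and blood, skeletal muscle, adipocyte, cartilage and bone, endothelial and pericyte, epithelial, neural and glial, and fibroblast cells. Some genes are on several lists. Each gene of a list was represented by 1 probe set, and lists with at least 5 measured genes were tested with camera, 28 on array A and 17 on array B. Camera ran with a preset correlation of 0.01 between genes and again with a correlation estimated from the data. Of 70 calls among 315 list tests, 18 were also made with the estimated correlation, which added 0 new calls.

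Genes were named by rule: on array A the 10 largest rises and 10 largest falls, and on array B the 5 largest of each, among called probe sets of 1 gene whose groups did not overlap. Where fewer than 3 passed, the 5 with the smallest p in each direction are given as values. Of each list, up to 4 called members with the smallest adjusted p could be named, or all of up to 6 called members. Changes are log2 differences with the standard error (SE) of the limma model, and group levels are log2 means ± SD over 4 replicates.

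The title numbers fall into 2 runs. Replicates 1 and 2 form the first number run and replicates 3 and 4 the second. Whether replicate numbers pair the samples was checked on deviations from group means. Same-numbered samples correlated at 0.32 to 0.72 on array A (median 0.59) and 0.24 to 0.6 on array B (median 0.48). Samples of the same run with another number reached medians of 0.57 and 0.39, and samples of different runs -0.7 to -0.27 and -0.59 to -0.18. After the run means were removed, same-numbered samples correlated at medians of 0.05 and 0.09. Fits with a replicate block, a number run block, or only 1 run, all planned, are therefore given beside the pooled counts where they differ by over 1.5 times. The correlation that camera estimated came from the fit without a block. Shifts between the runs that genes of a list share therefore enter it and can raise it.

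Other alternatives were quantile normalization, no filter, no intensity trend, array weights and leaving out each extract in turn. A fit without Oct-1 mutant unirradiated replicate 4, combined with the replicate block, and list tests by number run were added after the data were seen. So were the permutation tests of the control probe sets within number runs, the comparison of named genes with their other probe sets and the place of named genes on chromosome 1. For that comparison, probe sets with names ending in _x_at were left out. The procedure was tested on simulated data with 100 changed probe sets at each of 2 sizes, 0.5 and 1. False calls were counted once over both sizes. For irradiation in wild type on array A, 43 changes of 0.5 and 93 changes of 1 were recovered, with 1 false call in all. The replicate block recovered 68 and 96, with 9 false calls. For the difference of the irradiation effects on array A, 25 and 73 were recovered with 2 false calls, and 46 and 89 with 7 false calls with the replicate block. The 100 probe sets present on both array types were used to compare them, and genes were not taken as independent replicates. Across these probe sets the changes correlated at 0.79 for irradiation in wild type, 0.76 in the mutant, 0.7 for genotype in unirradiated and 0.78 in irradiated cells, but at 0.42 for the difference of the irradiation effects.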

Results

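Expression was measured in early-passage primary mouse embryonic fibroblasts of 2 genotypes, wild type and Oct-1 mutant, with and without irradiation, in 4 replicates per group on both array types. After filtering, array A measured 7760 distinct genes and array B 6533. Replicates of a group correlated at 0.9759 to 0.9958 on array A and 0.9731 to 0.9959 on array B over probe sets. Deviations from the group means followed the number run: the first component held 61.7% of their variance on array A and 49.6% on array B, and it separated replicates 1 and 2 from replicates 3 and 4 in each group. The 3 prime minus 5 prime signal of the Gapdh control on array A was 0.08 higher in irradiated arrays when labels were exchanged only within genotype and number run (exact permutation p = 0.034, adjusted p = 0.272 over 8 tests, smallest possible p = 0.0015). The other 7 tests of the Gapdh and beta-actin controls gave differences from -0.02 to 0.03 with an adjusted p of 0.971.

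**Figure D1:**
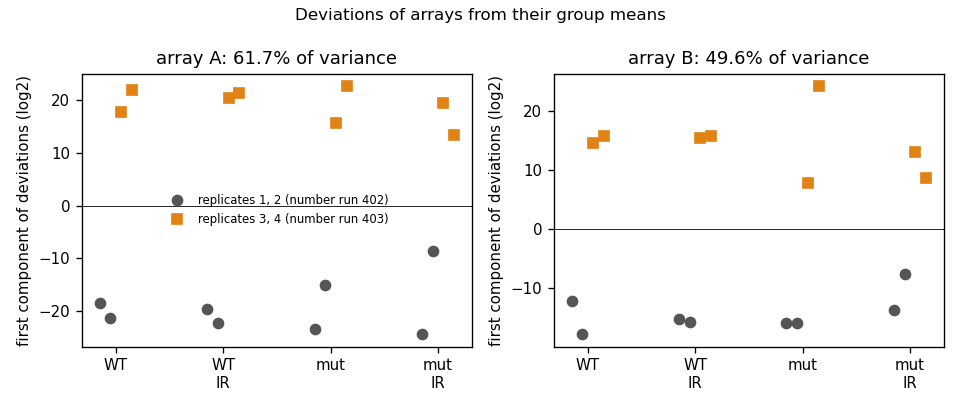
First principal component of each array's log2 deviation from its group mean, for array A (61.7% of the variance) and array B (49.6%), by group; circles are replicates 1 and 2 and squares replicates 3 and 4. In each group the 2 replicates of the first number run lie below 0 and the 2 of the second lie above.

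The first comparison asked which genes irradiation changed in wild type cells. Cdkn1a, the cyclin-dependent kinase inhibitor p21 and a p53 target, rose 4.29-fold (log2 2.1, SE 0.17), from 5.9 ± 0.3 to 8 ± 0.08 (n = 4 per group, adjusted p = 1.96e-06). Mdm2, the ubiquitin ligase that limits p53, rose 3.34-fold (log2 1.74, SE 0.3, adjusted p = 0.0027), and Pmaip1, the pro-apoptotic NOXA, rose 4.39-fold (log2 2.14, SE 0.31, adjusted p = 0.000547). Plk1, a mitotic kinase, fell by 1.57 (SE 0.08), from 9.29 ± 0.17 to 7.72 ± 0.05, with an adjusted p of 6.81e-08. Aspm, a spindle pole protein, fell by 2.04 (SE 0.19, adjusted p = 8.88e-06). The naming rule required that all 4 irradiated replicates of each of these probe sets lay beyond all 4 unirradiated ones.

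Further rises on array A were seen for Arap2 (2.86, SE 0.27), the antigen peptide transporter Tap1 (2.62, SE 0.18) and Ddit4l (2.07, SE 0.27). Also higher were the death-associated kinase Dapk1 (1.9, SE 0.13), the carbonyl reductase Dcxr (1.9, SE 0.11), the receptor Notch3 (1.87, SE 0.29) and Dcaf4 (1.81, SE 0.17). Falls on array A included the kinetochore genes Cenpf (-2.05, SE 0.33) and Cenpe (-1.45, SE 0.32), the mitotic kinase Aurka (-1.58, SE 0.11) and Depdc1a (-1.49, SE 0.13). The kinesins Kif2c (-1.4, SE 0.26), Kif23 (-1.32, SE 0.33) and Kif22 (-1.23, SE 0.17) fell as well. Cdc25b, a phosphatase that activates cyclin-dependent kinases, fell by 1.32 (SE 0.17). On array B the ubiquitin ligase Trim7 (2.19, SE 0.21), Zfp365 (2.09, SE 0.44), Tbc1d2 (1.93, SE 0.23) and the kinase Mapkapk3 (1.9, SE 0.35) rose. Gas2l3 (-2.05, SE 0.38), Depdc1b (-1.41, SE 0.23), the helicase Pif1 (-1.26, SE 0.21), the spindle checkpoint gene Bub1b (-1.02, SE 0.16) and the mitotic regulator Bora (-0.99, SE 0.19) fell. Of 17 named genes with other probe sets, 4 had none that moved at least 50% as far: Arap2 (0.09 and 0.51), Cenpf (-0.5), Aspm (-0.82 and -0.33) and Pif1 (-0.09 and -0.16), all on array B. The calls of Bora, Cenpe, Gas2l3, Kif23, Mapkapk3 and Zfp365 were each lost on leaving out any 1 of 2 to 12 extracts, with adjusted p up to 0.144. For Arap2, Tap1 and Cenpe the lower group mean was under 4.96, the mean the filter required. Background may hold it up, so such changes are read here and below as lower bounds for that probe set, not for others of the gene. That mark is a filter cut, and background itself was not measured.

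Of the 37 measured p53 targets on array A, 25 rose and 12 did not pass (31 rose when adjusted over the list alone). The list had a median of 0.79 and an adjusted p of 1.21e-34 (adjusted p = 0.00187 with an estimated correlation). Beside Dcxr and Tap1, Ei24 rose by 0.87 (SE 0.06) and Ercc5, a nucleotide excision repair endonuclease, by 1.19 (SE 0.13). The list median was 0.87 within the first number run and 0.6 within the second. On array B, Eda2r, a tumour necrosis factor receptor family member, rose by 1.71 (SE 0.17) and Slc19a2, a thiamine transporter, by 1 (SE 0.21). These were 2 of 6 measured targets over all genes and 2 adjusted over the list alone (list median 0.32, adjusted p = 0.000473; adjusted p = 0.0913 with an estimated correlation). That median was 0.53 within the first number run and 0.29 within the second.

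Of the 41 measured G2/M and mitosis genes on array A, 26 fell and 0 rose (31 fell when adjusted over the list alone). The median was -0.73 (adjusted p = 1.45e-39; adjusted p = 0.013 with an estimated correlation). Cks2, a subunit of mitotic kinases, fell by 0.87 (SE 0.07). The list median was -0.71 within the first number run and -0.72 within the second. On array B, 6 of 14 fell (9 adjusted over the list alone), with a median of -0.45 (adjusted p = 1.74e-17; adjusted p = 0.00179 with an estimated correlation). Nek2, a centrosomal kinase, fell by 0.88 (SE 0.13).

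Hox and positional genes, which set regional identity in the embryo, were lower: 7 of 27 fell on array A, 10 adjusted over the list alone and 11 with the replicate block. The median was -0.36 (adjusted p = 1.16e-09; adjusted p = 0.00683 with an estimated correlation). Hoxa10 fell by 0.92 (SE 0.16), the T-box factor Tbx15 by 0.57 (SE 0.08), Prrx1 by 0.45 (SE 0.08) and Hoxc8 by 0.43 (SE 0.09). The median was -0.42 within the first number run and -0.25 within the second. On array B, 0 of 15 passed over all genes and 1 fell when adjusted over the list alone. The median was -0.15 (adjusted p = 0.00101; adjusted p = 0.264 with an estimated correlation), against -0.28 within the first number run and -0.1 within the second.

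G1/S and DNA replication genes shifted up with a median of 0.17 on array A (adjusted p = 0.000163; adjusted p = 0.676 with an estimated correlation). Of 38 genes 3 rose over all genes, 5 adjusted over the list alone and 12 with the replicate block. These were Pole2 (0.52, SE 0.1), a subunit of DNA polymerase epsilon, the licensing factor Cdt1 (0.27, SE 0.07) and the helicase subunit Mcm7 (0.28, SE 0.08). On array B, 0 of 7 passed, with a list adjusted p of 0.0196 (adjusted p = 0.0913 with an estimated correlation). This call was lost within the first number run (adjusted p = 0.0766), within the second (0.133) and with no filter (0.136). NRF2 and antioxidant genes had a median of 0.14 (adjusted p = 6.99e-05; adjusted p = 0.0988 with an estimated correlation). Of 46 genes 4 rose: Sesn2 (0.97, SE 0.15), Ephx1 (0.45, SE 0.08), Hmox1 (0.48, SE 0.13) and Blvrb (0.44, SE 0.11). Sesn2 and Ephx1 are also on the p53 target list. Adjusted over the list alone, 7 rose and 1 fell, and with the replicate block 8 rose and 1 fell. Oxidative phosphorylation and TCA cycle genes had a median of 0.11 (adjusted p = 1.17e-05; adjusted p = 0.0988 with an estimated correlation). The complex I subunits Ndufb2 (0.33, SE 0.07) and Ndufa8 (0.21, SE 0.06) were the 2 of 71 that rose, against 3 adjusted over the list alone and 11 with the replicate block.

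Cholesterol synthesis genes had a median of -0.18 (adjusted p = 7.78e-05; adjusted p = 0.167 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, fell by 0.59 (SE 0.08), Sqle by 0.33 (SE 0.05) and Stard4 by 0.4 (SE 0.08). These were 3 of 19 over all genes and 5 adjusted over the list alone or with the replicate block. Of 17 interferon response genes 4 rose (5 adjusted over the list alone): Tap1, Ifi35 (0.55, SE 0.11), Ifitm3 (0.39, SE 0.08) and Lgals3bp (0.6, SE 0.14). That list had a median of 0.12 and an adjusted p of 0.0113 (adjusted p = 0.0988 with an estimated correlation). The median was 0.24 within the first number run and 0.11 within the second, where the adjusted p was 0.104, and with no filter the median was 0.01 and the adjusted p 0.187. Of 17 fibroblast markers, Prrx1, Twist1 (-0.55, SE 0.12) and Pdgfra (-0.69, SE 0.16) fell. The counts were 3 over all genes, 4 adjusted over the list alone and 5 with the replicate block. The median of that list was -0.03 and its adjusted p 0.0268 (adjusted p = 0.417 with an estimated correlation). Within the first number run the adjusted p was 0.182, and within the second the median was -0.06.

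The other 19 lists tested on array A had adjusted p from 0.0513 to 0.988. Apoptosis regulators had the lowest, and their adjusted p was 0.0419 with the replicate block. Of 29 genes 3 rose over all genes and adjusted over the list alone: Dapk1, the apoptosome gene Apaf1 (0.97, SE 0.13) and Bcl2l11 (0.56, SE 0.12). Single called members elsewhere were the mismatch repair gene Msh6 (1.05, SE 0.19) and the checkpoint kinase Chek2 (0.56, SE 0.1) of 40 DNA repair genes, Ldhb (1.1, SE 0.11) of 17 glycolysis genes and Acadvl (0.39, SE 0.07) of 21 fatty acid genes. Klf4 (0.84, SE 0.11) and Fosl1 (0.51, SE 0.09) rose among 24 immediate early genes, Dnajb1 (0.48, SE 0.1) among 20 heat shock genes, and Perp (1.29, SE 0.16) among 10 epithelial markers. Of 35 unfolded protein response genes Sesn2 rose and Xbp1 fell by 0.32 (SE 0.08), and of 7 endothelial and pericyte markers Notch3 rose. By limma over all genes, 0 NF-kB mediators of 17 passed, and 2 rose when adjusted over the list alone. With either adjustment 0 members passed in the lists of extracellular matrix (52 genes), TGF-beta and contractile (29), hypoxia (19), POU (10) and imprinted (17) genes. The same held for sex-linked genes (6) and for macrophage and blood (5), adipocyte (5) and neural (11) markers. Histones (2 genes), skeletal muscle (4) and cartilage and bone markers (4) were too few to test, and 0 of their members passed. On array B the 13 lists not called had adjusted p from 0.0566 to 0.991. Cholesterol synthesis genes there had an adjusted p of 0.0223 with the replicate block, and the interferon gene Ifi35 rose by 0.5 (SE 0.09).

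In all, 625 probe sets were called for irradiation in wild type by limma, 399 up and 226 down, and 117 of these changed more than 2-fold. With the replicate block the count was 1653 and with the number run block 1632, and all 625 remained called with the replicate block. Within the number runs the counts were 681 and 355.

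The next comparison asked which genes irradiation changed in Oct-1 mutant cells. Plk1 fell by 1.86 (SE 0.08), from 9.31 ± 0.1 to 7.45 ± 0.03 (n = 4 per group, adjusted p = 5.45e-09), Aspm by 2.61 (SE 0.19, adjusted p = 6.6e-07) and Aurka by 1.75 (SE 0.11, adjusted p = 2.49e-07). Tap1 rose 5.46-fold (log2 2.45, SE 0.18, adjusted p = 6.61e-07), Pmaip1 5.37-fold (log2 2.43, SE 0.31) and Mdm2 3.03-fold (log2 1.6, SE 0.3, adjusted p = 0.00484). Cdkn1a levels were 6.56 ± 0.31 without and 8.11 ± 0.23 with irradiation. Arap2 (2.21, SE 0.27), Notch3 (2.06, SE 0.29), Dapk1 (1.86, SE 0.13), the fatty acid transporter family member Slc27a3 (1.8, SE 0.28) rose on array A. So did Dcaf4 (1.76, SE 0.17), Dcxr (1.75, SE 0.11) and Tmem19 (1.72, SE 0.14).

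Falls on array A further included Cenpf (-2.42, SE 0.33), Kif2c (-1.76, SE 0.26), Depdc1a (-1.49, SE 0.13), Kif23 (-1.45, SE 0.33), the hyaluronan receptor Hmmr (-1.35, SE 0.32), the spindle kinesin Kif11 (-1.33, SE 0.16) and Kif22 (-1.32, SE 0.17). On array B, the anoctamin Ano3 (2.54, SE 0.41), Zfp365 (2.43, SE 0.44), Trim7 (2.07, SE 0.21) and Tbc1d2 (1.71, SE 0.23) rose. Gas2l3 (-2.09, SE 0.19), Depdc1b (-1.59, SE 0.23), Pif1 (-1.28, SE 0.21), Prr11 (-1.28, SE 0.19) and Bub1b (-1.22, SE 0.16) fell. Of 17 named genes with other probe sets, 5 had none that moved at least 50% as far: Arap2 (0.14 and 0.81), Cenpf (-0.75), Aspm (-0.7 and -0.16), Ano3 (0.56) and Pif1 (-0.22 and -0.14), all on array B. The calls of Hmmr, Kif23 and Zfp365 were each lost on leaving out any 1 of 4 extracts, with adjusted p up to 0.0745. For Arap2 and Slc27a3 the mean without irradiation was under 4.96, the mean the filter required. The rises of these probe sets are therefore lower bounds.

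Of the 37 p53 targets on array A, 26 rose (30 adjusted over the list alone). The median was 0.69 (adjusted p = 4.89e-30; adjusted p = 0.00362 with an estimated correlation). Btg2, an antiproliferative gene, rose by 1.02 (SE 0.11). Of the 41 G2/M and mitosis genes 31 fell (38 adjusted over the list alone), with a median of -0.76 (adjusted p = 2.55e-43; adjusted p = 0.00921 with an estimated correlation). Among them was Cdc20, an activator of the anaphase-promoting complex (-0.78, SE 0.07). Hox and positional genes had a median of -0.28 (adjusted p = 3.57e-09; adjusted p = 0.00851 with an estimated correlation). Of 27 genes 7 fell, 10 adjusted over the list alone and 11 with the replicate block. Hoxa10 fell by 1.07 (SE 0.16), Tbx15 by 0.7 (SE 0.08), Meis1, a Hox cofactor, by 0.65 (SE 0.11) and Hoxc8 by 0.51 (SE 0.09). Within the first and the second number run the medians were 0.87 and 0.64 for p53 targets, -0.75 and -0.76 for G2/M genes, and -0.4 and -0.23 for Hox genes.

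On array B, 5 of 14 G2/M genes fell (7 adjusted over the list alone), with a median of -0.35 (adjusted p = 3.31e-13; adjusted p = 0.00619 with an estimated correlation), against -0.52 within the first number run and -0.23 within the second. Eda2r (1.32, SE 0.17) was the 1 called p53 target of 6, against 3 adjusted over the list alone (list adjusted p = 0.00228; adjusted p = 0.164 with an estimated correlation). Of 15 Hox genes 0 passed over all genes and 3 fell when adjusted over the list alone (list median -0.25, adjusted p = 3.24e-07; adjusted p = 0.0904 with an estimated correlation). That median was -0.38 without Oct-1 mutant unirradiated replicate 4, -0.4 within the first number run and -0.21 within the second.

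G1/S genes had a median of 0.16 on array A (adjusted p = 0.000347; adjusted p = 0.631 with an estimated correlation). Of 38 genes 4 rose over all genes and over the list alone: Pcna, the DNA polymerase clamp (0.34, SE 0.07), Mcm7 (0.34, SE 0.08), Pole2 (0.43, SE 0.1) and Cdt1 (0.27, SE 0.07). With the replicate block 12 rose, and without Oct-1 mutant unirradiated replicate 4 the median was 0.09. NRF2 and antioxidant genes had a median of 0.13 (adjusted p = 0.000347; adjusted p = 0.221 with an estimated correlation). Of 46 genes 4 rose, 5 adjusted over the list alone and 10 with the replicate block, Hmox1 by 0.57 (SE 0.13) and Gstm1 by 0.33 (SE 0.09) among them. Oxidative phosphorylation genes had a median of 0.1 (adjusted p = 0.000716; adjusted p = 0.279 with an estimated correlation). Ndufv1 (0.33, SE 0.07) and Ndufs4 (0.26, SE 0.06) were the 2 of 71 that rose over all genes and over the list alone, against 17 with the replicate block.

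Cholesterol synthesis genes had a median of -0.2 (adjusted p = 0.000372; adjusted p = 0.279 with an estimated correlation). Hmgcs1 (-0.56, SE 0.08), Sqle (-0.39, SE 0.05) and Msmo1 (-0.39, SE 0.09) were the 3 of 19 that fell, also when adjusted over the list alone, against 5 with the replicate block. Immediate early genes had a median of 0.13 (adjusted p = 0.0424; adjusted p = 0.631 with an estimated correlation). Fosl1 (0.68, SE 0.09) and Klf4 (0.53, SE 0.11) were the 2 of 24 that rose, also when adjusted over the list alone. That list had a median of 0.3 within the first number run and 0 within the second, and an adjusted p of 0.0819 without Oct-1 mutant unirradiated replicate 4. The other 20 lists on array A had adjusted p from 0.101 to 0.977. Their called members were Tap1, Dapk1, Apaf1 (0.87, SE 0.13), Bcl2l11 (0.72, SE 0.12) and Msh6 (1.13, SE 0.19). Further members were Ldhb (0.99, SE 0.11), Acadvl (0.27, SE 0.07), Hadhb (0.29, SE 0.08), Elovl6 (-0.42, SE 0.09), Dnajb1 (0.41, SE 0.1) and Sesn2 (0.7, SE 0.15). The rest were Lif (0.61, SE 0.12), Plod2 (0.63, SE 0.16), Perp (1.18, SE 0.16), Notch3, Prrx1 (-0.38, SE 0.08), Pdgfra (-0.75, SE 0.16) and Twist1 (-0.44, SE 0.12). The fibroblast markers had a median of 0.01 but a mean of -0.11, with an adjusted p of 0.101. Of the untested skeletal muscle markers Mef2c fell by 0.56 (SE 0.13). On array B the 14 lists not called had adjusted p from 0.101 to 0.971. There NF-kB mediators had an adjusted p of 0.0447 with the number run block.

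By limma, 724 probe sets were called for irradiation in the mutant, 448 up and 276 down, 128 of them by more than 2-fold. With the replicate block the count was 1938 and with the number run block 1928, and within the number runs it was 794 and 357.

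**Figure D2:**
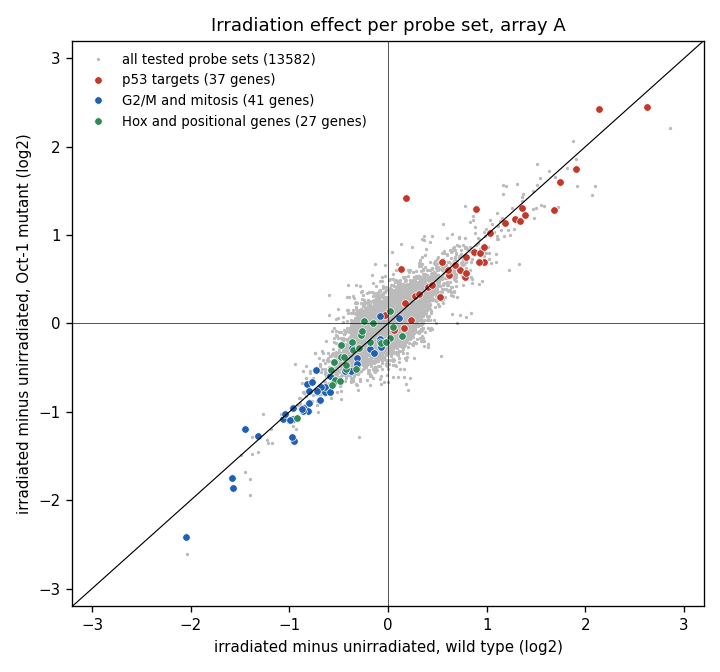
Log2 irradiation effect per probe set on array A in wild type (horizontal) and Oct-1 mutant cells (vertical), means of 4 replicates per group, with p53 targets, G2/M genes and Hox genes coloured and the line of equal effects drawn. Most p53 targets lie in the upper right and most G2/M genes in the lower left (medians 0.79 and 0.69, and -0.73 and -0.76).

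The question in the series title, how radiation acts in both genotypes, was tested through the difference of the irradiation effects, mutant minus wild type. The difference was -0.29 for Plk1 (95% interval -0.54 to -0.04), -0.55 for Cdkn1a (-1.05 to -0.05), -0.14 for Mdm2 (-1.05 to 0.76) and -0.17 for Tap1 (-0.72 to 0.37), with an adjusted p of 1 each. Of the 27084 probe sets 0 were called by limma, with 395 at an unadjusted p under 0.05 against 1354 that chance alone would give. This fit keeps the differences between the runs in its residual variance, which makes its p-values larger, so 1354 is not its own count by chance. With the replicate block 0 were called and 837 had an unadjusted p under 0.05, still fewer than 1354. The runs therefore do not account for all of the shortfall, and the rest was not tested. Without wild type irradiated replicate 2 the count called was 1. For the 2034 probe sets called for irradiation averaged over both genotypes, the median half-width of the 95% interval of the difference was 0.32, and 96.7% of the intervals lay within a change of 1.

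The probe sets with the smallest p on array A were Ptprv (1.24, SE 0.33), a phosphatase of the p53 target list, the ADP-ribosyltransferase Parp9 (0.58, SE 0.16), Inhbb (0.35, SE 0.1), Desi1 (0.34, SE 0.1) and Clcn3 (0.52, SE 0.17). In the other direction they were Mtx2 (-0.34, SE 0.11), Klf4 (-0.62, SE 0.2), Abca1 (-0.42, SE 0.14), Uqcr10 (-0.49, SE 0.16) and Carmil1 (-0.52, SE 0.18). Of 10 of these genes with other probe sets, 7 had none that moved at least 50% as far in the same direction: Desi1 (-0.26 and 0.14), Clcn3 (-0.08 and -0.17), Klf4 (-0.3), Uqcr10 (-0.2), Slc25a27 (0.09), Cox10 (0.19) and Zfp655 (0.13 and 0.29). Ptprv levels were 4.76 ± 0.26 and 4.94 ± 0.12 in wild type and 6.84 ± 0.59 and 8.26 ± 0.29 in mutant cells without and with irradiation (adjusted p = 1). Both wild type means of Ptprv, the wild type unirradiated mean of Tap1 and 2 of the 4 means of Clcn3 were under 4.96, the mean the filter required, so the irradiation effects there, and the differences of these genes, are not measured exactly. On array B they were Cenpa (0.38, SE 0.1), Zranb3 (0.34, SE 0.09), Golga7b (0.24, SE 0.07), Runx1t1 (0.34, SE 0.1) and Slc25a27 (0.33, SE 0.1), and with the other sign Ddx58 (-0.51, SE 0.1), Cox10 (-1.03, SE 0.26), Rnf113a2 (-0.48, SE 0.14), Rubcn (-0.41, SE 0.12) and Zfp655 (-0.5, SE 0.15), each with an adjusted p of 0.999. Of the 45 list tests 1 was called: the 41 G2/M genes had a median difference of -0.1 on array A (adjusted p = 0.00924; adjusted p = 0.975 with an estimated correlation). Adjusted over the list alone 0 of its members passed, and the list's adjusted p was 0.12 within the first number run, 0.0165 within the second and 0.0788 with no filter. The median was -0.06 within the first number run and -0.11 within the second. The other 27 lists on array A had adjusted p from 0.216 to 0.934 and the 17 on array B from 0.377 to 0.974.

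Of the probe sets called up by irradiation, 293 were called in both genotypes against 9.3 for independent lists, and of those called down 167 against 3.8. Of the 625 called in wild type, 624 had the same sign in the mutant. Over all tested probe sets, which are not independent replicates, the 2 effects correlated at 0.81 on array A and 0.67 on array B.

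Averaged over both genotypes, irradiation called 2034 probe sets by limma, 1220 up and 814 down, against 4040 with the replicate block and 3985 with the number run block. Tap1 rose by at least 2.54 (SE 0.13; its wild type unirradiated mean was under 4.96), Pmaip1 by 2.28 (SE 0.22) and Cdkn1a by 1.82 (SE 0.12), and Aspm fell by 2.32 (SE 0.14) and Plk1 by 1.71 (SE 0.06). On array A, 32 of 37 p53 targets rose (33 adjusted over the list alone), 34 of 41 G2/M genes fell (39 adjusted over the list alone) and 11 of 27 Hox genes fell (13 adjusted over the list alone). The adjusted p-values of these lists were 1.43e-30, 2.31e-39 and 4.4e-10, and 0.00334, 0.0133 and 0.00569 with an estimated correlation. G1/S genes (9 of 38 up, among them Pole2, 0.47, SE 0.07) had an adjusted p of 5.11e-05. NRF2 and antioxidant genes (10 of 46 up, among them Sesn2, also a p53 target, 0.84, SE 0.1) had 3.76e-05. Oxidative phosphorylation genes (20 of 71 up, Uqcrc1 0.27, SE 0.05) and cholesterol synthesis genes (7 of 19 down, Hmgcs1 -0.58, SE 0.05) had 2.05e-05 and 8.61e-05. Adjusted over the list alone these counts were 12, 16, 22 and 7, and none of the 4 lists was called with an estimated correlation (adjusted p = 0.587, 0.128, 0.131 and 0.206 with an estimated correlation). On array B 5 lists were called, and only the G2/M list (7 of 14 down, 9 adjusted over the list alone; adjusted p = 2.11e-17) was also called with an estimated correlation (adjusted p = 0.00183 with an estimated correlation). The calls there of G1/S genes (adjusted p = 0.0402) and cholesterol synthesis genes (adjusted p = 0.0477) were lost within the first number run (0.177 each), with no filter (0.0606 each) and without Oct-1 mutant unirradiated replicate 4 (0.0623 and 0.0757), and that of G1/S genes also within the second number run (0.143). NF-kB mediators on array B had an adjusted p of 0.0511, and 0.0241 with the replicate block. They were not called with an estimated correlation in the fit without a block.

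**Figure D3:**
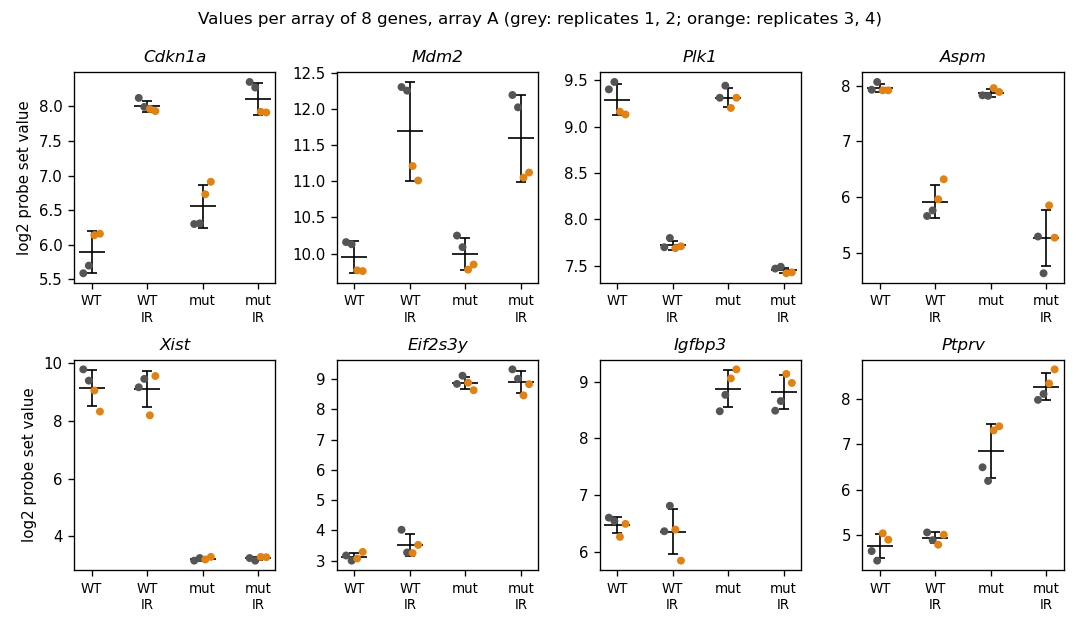
Log2 probe set values on array A of 8 genes in the 4 groups, 1 point per array, with group mean and SD as bars; grey points are replicates 1 and 2, orange points replicates 3 and 4. Cdkn1a and Mdm2 are higher and Plk1 and Aspm lower in irradiated cells of both genotypes, and Xist is at 8.19 or above in wild type and at 3.29 or below in mutant arrays.

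The genotype comparison asked how Oct-1 mutant cells differ from wild type cells, first without irradiation. Xist, the noncoding RNA of the inactive X chromosome, was at least 60.2-fold lower in the mutant (log2 -5.91, SE 0.28), at 3.22 ± 0.06 against 9.14 ± 0.62 (n = 4 per group, adjusted p = 2.93e-09), and the Y-linked Eif2s3y was at least 53.3-fold higher (log2 5.74, SE 0.19), at 8.87 ± 0.2 against 3.13 ± 0.13 (adjusted p = 1.39e-11). The interferon-inducible Ifi202b was at least 30-fold higher (log2 4.91, SE 0.19), at 8.64 ± 0.44 against 3.74 ± 0.22 (adjusted p = 1.25e-10), and Igfbp3, a binding protein of insulin-like growth factors, 5.3-fold higher (log2 2.41, SE 0.2, adjusted p = 2.67e-06). Ahcy, S-adenosylhomocysteine hydrolase, was 6.68-fold lower (log2 -2.74, SE 0.08, adjusted p = 7.42e-12). For Pclaf, a PCNA-binding protein, 1 probe set was at least 13-fold lower (log2 -3.7, SE 0.19, adjusted p = 9.41e-09), but the other on array A was at -0.08 (SE 0.11, adjusted p = 0.844).

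Other genes with a probe set higher in the mutant on array A were the peroxiredoxin Prdx2 (3.36, SE 0.24), cathepsin E or Ctse (3.16, SE 0.5) and Fxyd6 (2.69, SE 0.26). The same held for the matrix proteoglycans Dcn (2.25, SE 0.33) and Prelp (2.15, SE 0.24), Ptprv (2.08, SE 0.23) and the R-spondin receptor Lgr5 (2.05, SE 0.18). Probe sets were lower for the noncoding Gas5 (-2.12, SE 0.18), Limd1 (-1.6, SE 0.17), the lipase Lipg (-1.53, SE 0.29), Ywhaz (-1.27, SE 0.13), the RNA-binding Elavl2 (-1.26, SE 0.29) and the cartilage collagen Col2a1 (-1.25, SE 0.15). On array B, Igfbp3 (2.39, SE 0.26), Afap1l2 (1.61, SE 0.27), the ubiquitin ligase Fbxo32 (1.43, SE 0.12), Igf1 (1.39, SE 0.28) and Cthrc1 (1.38, SE 0.08) were higher. Pank4 (-2.28, SE 0.15), Shisa4 (-1.46, SE 0.09), Lancl3 (-1.12, SE 0.21), Thsd7a (-0.99, SE 0.13) and the kinase Mapk8 (-0.92, SE 0.17) were lower. Of 14 named genes with other probe sets, 9 had none that moved at least 50% as far. These were Pclaf, Prdx2 (other probe set -0.05, adjusted p = 0.92), Ctse (0.26, adjusted p = 0.192), Limd1 (-0.06, adjusted p = 0.935) and Ywhaz (-0.46 to 0.12 in 4 others), which were called in 1 probe set only. The rest were Afap1l2 (0.2), Thsd7a (-0.27), Mapk8 (0.03 to 0.3) and, on array B, Eif2s3y (0.04). A further Gas5 probe set was at -0.76 (SE 0.07). Gas5 lies among the 100 tested genes nearest the mutated gene on chromosome 1 and Ifi202b just beyond them, the 54th tested gene on its side. Ctse, Prelp, Ptprv and Shisa4 lie on that chromosome too, 111 to 150 tested genes away. The calls of Afap1l2, Elavl2, Igf1, Lancl3 and Mapk8 were each lost on leaving out any 1 of 1 to 13 extracts, with adjusted p up to 0.149. The lower group mean was under 4.96, the mean the filter required, for Xist, Pclaf, Elavl2, Eif2s3y, Ifi202b, Prdx2, Ctse, Fxyd6, Ptprv and Tap1. Background may hold it up, so the changes of these probe sets are lower bounds. For Pclaf, Prdx2, Ctse and Eif2s3y this holds for the named probe set only, since other probe sets moved far less.

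Interferon response genes were higher, 5 of 17 over all genes and 10 adjusted over the list alone, with a median of 0.31 (adjusted p = 8.33e-07; adjusted p = 0.00503 with an estimated correlation). Beside Ifi202b these were Lgals3bp (1.21, SE 0.14), Tap1 (0.79, SE 0.18), Ifitm3 (0.57, SE 0.08) and the transcription factor Irf1 (0.47, SE 0.11). The list median was 0.29 within the first number run and 0.26 within the second. The imprinted list holds genes known for expression from 1 parental allele, which was not measured in these cells. On this list, which shares Dcn with the fibroblast markers, 4 of 17 genes were higher. Adjusted over the list alone 6 were higher, and 7 with the replicate block. The median was 0.22 (adjusted p = 7.36e-05; adjusted p = 0.0096 with an estimated correlation). Dlk1 was higher by 1.16 (SE 0.09), Peg3 by 0.66 (SE 0.06), the kinase inhibitor Cdkn1c by 0.68 (SE 0.16) and Dcn by the value above, and the list median was 0.29 within the first and 0.18 within the second number run. Xist and Eif2s3y separated the genotypes on all 16 arrays of type A, in the pattern of female wild type and male mutant cells. The list differences and the sex-linked differences therefore lie between the same arrays, and genotype cannot be told apart from sex here.

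Of 6 sex-linked marker genes 1 was higher and 3 lower (1 and 5 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.000202; adjusted p = 0.079 with an estimated correlation). Among them were the X-linked Eif2s3x (-0.73, SE 0.08) and Ddx3x (-0.54, SE 0.1). Extracellular matrix genes had a median of 0.22 (adjusted p = 9.42e-07; adjusted p = 0.347 with an estimated correlation). Of 52 genes 8 were higher and 1 lower, 15 and 3 adjusted over the list alone, and 24 and 3 with the replicate block. Timp3, an inhibitor of matrix metalloproteinases, was higher by 1.13 (SE 0.14), the microfibril gene Mfap2 by 0.47 (SE 0.07), and the matrix Gla protein gene Mgp lower (-0.8, SE 0.12). Without Oct-1 mutant unirradiated replicate 4 this median was 0.14, and it was 0.14 within the first number run and 0.31 within the second. Fibroblast markers had a median of 0.19 (adjusted p = 0.00265; adjusted p = 0.256 with an estimated correlation). Dcn was the 1 of 17 higher, against 3 adjusted over the list alone and 7 with the replicate block, and a median of 0.1 without Oct-1 mutant unirradiated replicate 4.

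Cholesterol synthesis genes had a median of 0.26 (adjusted p = 8.33e-07; adjusted p = 0.079 with an estimated correlation). Sqle (0.34, SE 0.05), Dhcr7 (0.75, SE 0.17), Cyp51 (0.36, SE 0.09), Idi1 (0.33, SE 0.08) and Pmvk (0.48, SE 0.13) were the 5 of 19 higher, against 11 adjusted over the list alone and 9 with the replicate block. NRF2 and antioxidant genes had a median of 0.15 (adjusted p = 1.08e-06; adjusted p = 0.0735 with an estimated correlation). Of 46 genes 11 were higher, and 17 higher and 2 lower both when adjusted over the list alone and with the replicate block. The glutathione peroxidases Gpx3 (1.39, SE 0.11) and Gpx7 (0.56, SE 0.07) and Blvrb (0.74, SE 0.11) were among them. G1/S genes had a median of -0.14 (adjusted p = 7.36e-05; adjusted p = 0.463 with an estimated correlation). Of 38 genes 0 passed by limma over all genes or over the list alone and 10 lower with the replicate block. Of 37 p53 targets 5 were higher, and 5 higher and 1 lower when adjusted over the list alone (median 0.13, adjusted p = 0.00833; adjusted p = 0.359 with an estimated correlation), with Ephx1 (0.43, SE 0.08), Dcxr (0.58, SE 0.11) and Trp53inp1 (0.73, SE 0.18) beside Ptprv and Tap1.

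The other 19 lists on array A had adjusted p from 0.0531 to 0.926. Hox and positional genes went both ways, with 5 of 27 higher and 1 lower, 9 and 5 adjusted over the list alone: Hoxc8 (0.78, SE 0.09), Meis1 (0.78, SE 0.11), En1 (0.7, SE 0.17), Prrx2 (0.58, SE 0.13) and Hoxd8 (0.55, SE 0.12) were higher and Hoxa10 (-0.71, SE 0.16) lower. The list's adjusted p of 0.0531 was 0.0468 with the replicate block. With the number run block, unfolded protein response genes and TGF-beta and contractile genes had an adjusted p of 0.049. None of these 19 lists was called with an estimated correlation in the fit without a block. Of the 41 G2/M genes Pttg1 (-0.68, SE 0.1) and Kif23 (-0.52, SE 0.11) were lower (2 adjusted over the list alone), and the list's adjusted p of 0.0925 was 0.0452 with the replicate block. Other called members were the DNA damage kinase Atm in 1 probe set (-1.18, SE 0.3) and Snapc3 of the snRNA activating complex (-0.71, SE 0.1). The Atm probe set on array B was at -0.27 in irradiated cells. Called too were the chemokines Ccl2 (0.5, SE 0.08) and Ccl7 (0.62, SE 0.1), Klf4 (0.93, SE 0.11), Nr4a1 (0.55, SE 0.08), Cebpb (0.36, SE 0.07) and Hyou1 (0.46, SE 0.11). The rest were Tgfbi (0.64, SE 0.15), Dapk1 (0.5, SE 0.13), Ldhb (0.57, SE 0.11), Dlat (-0.32, SE 0.07), Fabp4 (-0.5, SE 0.13) and Col2a1. On array B 1 of 17 lists was called, with the centromeric histone Cenpa (-0.36, SE 0.07) the 1 of 14 G2/M genes lower over all genes and over the list alone (adjusted p = 0.0202; adjusted p = 0.799 with an estimated correlation). That call was lost within the first number run (adjusted p = 0.158), within the second (0.132) and without Oct-1 mutant unirradiated replicate 4 (0.129).

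By limma, 585 probe sets were called, 394 higher and 191 lower in the mutant, 98 of them by more than 2-fold. The count was 1740 with the replicate block, 1683 with the number run block, 512 and 662 within the runs, and 380 without wild type unirradiated replicate 1 and also without replicate 2.

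In irradiated cells the genotypes were compared again. Ifi202b was at least 24.5-fold higher in the mutant (log2 4.61, SE 0.19, n = 4 per group, adjusted p = 3.13e-10), Igfbp3 5.53-fold higher (log2 2.47, SE 0.2) and Ptprv at least 10-fold higher (log2 3.33, SE 0.23, adjusted p = 3.9e-07). Ahcy was 6.51-fold lower (log2 -2.7, SE 0.08). For Pclaf 1 probe set was at least 20.3-fold lower (log2 -4.34, SE 0.19, adjusted p = 1.05e-09), but the other on array A was at -0.18 (SE 0.11, adjusted p = 0.501). Xist (-5.85, SE 0.28) and Eif2s3y (5.39, SE 0.19) differed here too. Further probe sets higher on array A were those of Prdx2 (3.7, SE 0.24), Ctse (3.25, SE 0.5), Fxyd6 (2.37, SE 0.26), Srpx (2.17, SE 0.22), Prelp (1.99, SE 0.24) and Lgr5 (1.98, SE 0.18). Lower ones were those of Gas5 (-1.99, SE 0.18), Lipg (-1.62, SE 0.29), Limd1 (-1.5, SE 0.17), Atm (-1.44, SE 0.3), Ywhaz (-1.34, SE 0.13) and Col2a1 (-1.29, SE 0.15). On array B, Igfbp3 (2.51, SE 0.26), Igf1 (1.55, SE 0.28), the collagen Col8a2 (1.39, SE 0.23), Fbxo32 (1.37, SE 0.12) and the Wnt antagonist Sfrp1 (1.23, SE 0.15) were higher. Pank4 (-2.66, SE 0.15), Thg1l (-1.96, SE 0.3), Shisa4 (-1.37, SE 0.09), the BMP receptor Bmpr1b (-1.3, SE 0.21) and Btbd11 (-1.26, SE 0.22) were lower. Of 15 named genes with other probe sets, 8 had none that moved at least 50% as far. These were Pclaf, Prdx2 (other probe set 0.07), Ctse (0.12), Limd1 (-0.13), Ywhaz (-0.14 to 0.12 in 4 others) and Bmpr1b (-0.48 and -0.1). Atm (-0.27) and Eif2s3y (0.08) were the others, each from a probe set on array B. A further Gas5 probe set was at -0.64 (SE 0.07). The calls of Btbd11, Col8a2 and Igf1 were each lost on leaving out any 1 of 4 to 5 extracts, with adjusted p up to 0.0968. For Ifi202b, Ptprv, Pclaf, Xist, Eif2s3y, Prdx2, Ctse, Fxyd6 and Lipg the lower group mean was under 4.96, the mean the filter required. The changes of these probe sets are therefore lower bounds. For Pclaf, Prdx2, Ctse and Eif2s3y this holds for the named probe set only, since other probe sets moved far less.

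Interferon response genes had a median of 0.31 (adjusted p = 5.92e-05; adjusted p = 0.016 with an estimated correlation). Of 17 genes 4 were higher, 8 adjusted over the list alone and 8 with the replicate block, among them Lgals3bp (1.06, SE 0.14) and the ubiquitin ligase Trim25 (0.46, SE 0.11). Imprinted genes had a median of 0.2 (adjusted p = 6.27e-05; adjusted p = 0.016 with an estimated correlation). Of 17 genes 5 were higher and 7 adjusted over the list alone, among them Dlk1 (1.2, SE 0.09) and Dcn (1.77, SE 0.33). Within the first and the second number run the medians were 0.24 and 0.22 for interferon genes and 0.18 and 0.2 for imprinted genes. Extracellular matrix genes had a median of 0.27 (adjusted p = 3.84e-09; adjusted p = 0.271 with an estimated correlation). Of 52 genes 13 were higher and 2 lower, 19 and 3 adjusted over the list alone, and 25 and 2 with the replicate block. Timp3 was higher by 1.34 (SE 0.14), the collagen-binding Fmod by 0.78 (SE 0.12), and Mgp lower (-0.85, SE 0.12).

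Cholesterol synthesis genes had a median of 0.27 (adjusted p = 1.3e-07; adjusted p = 0.0717 with an estimated correlation), with 4 of 19 higher and 8 both when adjusted over the list alone and with the replicate block: Cyp51 (0.46, SE 0.09), Ebp (0.36, SE 0.08), Fdft1 (0.33, SE 0.08) and Sqle (0.27, SE 0.05). NRF2 and antioxidant genes had a median of 0.13 (adjusted p = 4.38e-06; adjusted p = 0.0717 with an estimated correlation). Of 46 genes 11 were higher and 14 adjusted over the list alone, Gpx3 (1.5, SE 0.11) and Gstm1 (0.48, SE 0.09) among them. Fibroblast markers had a median of 0.25 (adjusted p = 0.000307; adjusted p = 0.16 with an estimated correlation), with 1 of 17 higher, 2 adjusted over the list alone and 8 with the replicate block. Sex-linked genes had a median of -0.55 (adjusted p = 0.000487; adjusted p = 0.103 with an estimated correlation), with 1 of 6 higher and 2 lower, 1 and 5 adjusted over the list alone, and 1 and 4 with the replicate block, and an adjusted p of 0.154 with no filter.

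Lists shifted down were G1/S (median -0.11, adjusted p = 0.000113; adjusted p = 0.486 with an estimated correlation), G2/M (median -0.14, adjusted p = 4.76e-05; adjusted p = 0.361 with an estimated correlation) and DNA repair (median -0.09, adjusted p = 0.0177; adjusted p = 0.16 with an estimated correlation). Of 38 G1/S genes 0 passed by limma over all genes or over the list alone and 8 were lower with the replicate block. Kif23 (-0.63, SE 0.11) and Pttg1 (-0.52, SE 0.1) were the 2 of 41 G2/M genes lower, also when adjusted over the list alone, against 7 with the replicate block. Atm was the 1 of 40 DNA repair genes lower, also when adjusted over the list alone, against 2 with the replicate block, and the DNA repair list's adjusted p was 0.15 within the second number run. The other 18 lists on array A had adjusted p from 0.06 to 0.969, the lowest for Hox genes (4 of 27 higher, 2 lower, 9 and 5 adjusted over the list alone), whose adjusted p was 0.0431 with the replicate block. Hoxa9 (-0.59, SE 0.14), Hoxa10 (-0.86, SE 0.16) and Snapc3 (-0.94, SE 0.1) were lower and Hoxd8 (0.69, SE 0.12), Meis2 (0.66, SE 0.17), Tgfbi (0.78, SE 0.15) and Ccl7 (0.69, SE 0.1) higher. On array B 0 of 17 lists were called, with adjusted p from 0.0995 to 0.989.

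By limma, 565 probe sets were called in irradiated cells, 383 higher and 182 lower in the mutant. The count was 1632 with the replicate block, 1621 with the number run block, and 528 and 601 within the runs. Of the probe sets called in unirradiated and irradiated cells, 260 were higher in both against 9.3 for independent lists and 115 lower in both against 2.1, and 582 of the 585 had the same sign.

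Averaged over irradiation, genotype called 1696 probe sets by limma, 1022 higher and 674 lower in the mutant, against 3769 with the replicate block and 3712 with the number run block. Ifi202b was higher by at least 4.76 (SE 0.13, with both wild type means under 4.96), Igfbp3 by 2.44 (SE 0.14) and Gpx3 by 1.44 (SE 0.08). Ahcy (-2.72, SE 0.06) and probe sets of Gas5 (-2.05, SE 0.13) and Atm (-1.31, SE 0.21) were lower. A further Gas5 probe set was at -0.7. The Atm probe set on array B was at -0.27 in irradiated cells (limma adjusted p = 0.563), so the fall of Atm rests on 1 probe set. On array A 12 of 28 lists were called, and 2 of them with an estimated correlation: interferon response genes (7 of 17 higher, 10 adjusted over the list alone; adjusted p = 5.93e-06, and adjusted p = 0.00963 with an estimated correlation) and imprinted genes (6 of 17 higher, 7 adjusted over the list alone; adjusted p = 6.47e-05, and adjusted p = 0.00963 with an estimated correlation). Hox genes, with 9 of 27 higher and 5 lower (13 and 5 adjusted over the list alone), were called here (adjusted p = 0.045; adjusted p = 0.26 with an estimated correlation), but not within the second number run (adjusted p = 0.115) or with no filter (0.347). Calls were also lost for p53 targets without Oct-1 mutant unirradiated replicate 4 (adjusted p = 0.0648), for DNA repair genes within the second number run (0.0927) and for sex-linked genes with no filter (0.0852). On array B the G2/M list was the 1 of 17 called (adjusted p = 0.00938; adjusted p = 0.798 with an estimated correlation), and it was not called within the second number run (0.222). With the replicate block, unfolded protein response genes (adjusted p = 0.0352), apoptosis regulators and TGF-beta and contractile genes (adjusted p = 0.0397 each) were called as well. None of them was called with an estimated correlation in the fit without a block. Extracellular matrix genes were higher in 18 of 52 cases and lower in 3, 24 and 3 adjusted over the list alone and 37 and 3 with the replicate block (median 0.25, adjusted p = 1.44e-08; adjusted p = 0.26 with an estimated correlation). That median was 0.16 within the first number run.

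**Figure D4:**
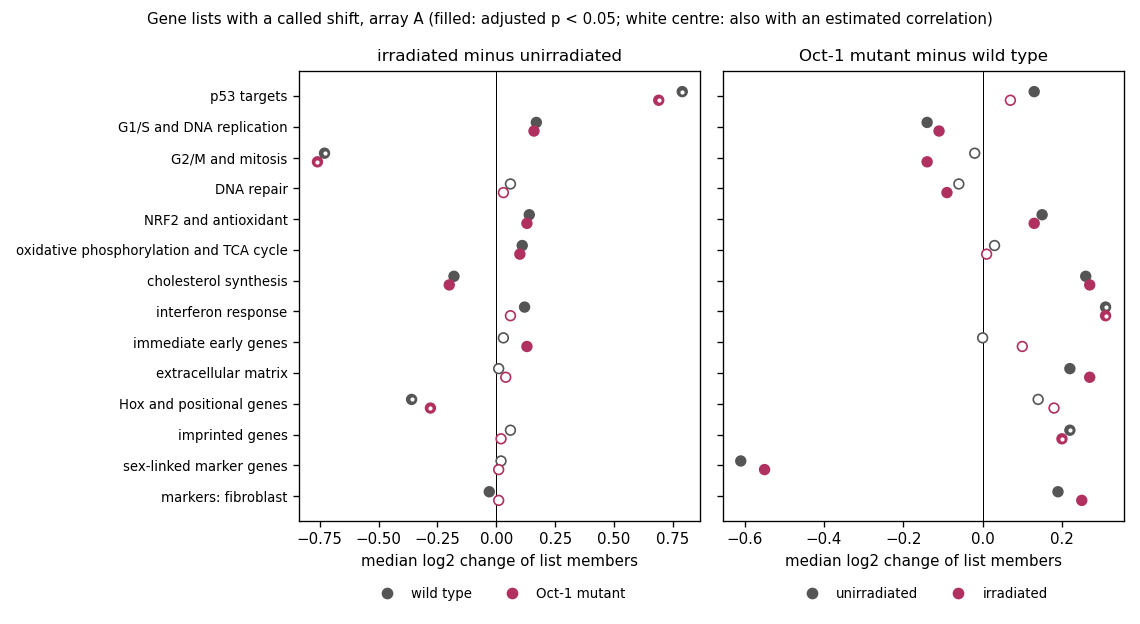
Median log2 change of the members of gene lists on array A, irradiated minus unirradiated in each genotype (left) and Oct-1 mutant minus wild type in each irradiation state (right); filled points have an adjusted p under 0.05 and a white centre marks those also called with an estimated correlation. The p53, G2/M and Hox lists carry white centres for irradiation, and the interferon and imprinted lists for genotype.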

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

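The fits without Oct-1 mutant unirradiated replicate 4 combined with the replicate block, and the list tests without it, were chosen only after its control signals were seen. In Oct-1 mutant unirradiated replicate 4 the control probe sets for 18S ribosomal RNA lay far from the other 3 replicates on both array types. On array A its values were 9.38 (3 prime; others 4.64 to 4.87), 9.2 (5 prime; 3.53 to 3.75) and 8.01 (middle; 2.59 to 2.73). On array B they were 8.76 (others 4.8 to 4.84), 9.3 (4.17 to 4.25) and 7.96 (3.08 to 3.21). Without this extract and with the replicate block, 1242 probe sets were called for genotype in unirradiated cells against 1740 with the block alone. The cause of the high signal was not tested.

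Single values apart from their replicates were the 18S 3 prime control of wild type irradiated replicate 3 on array B, 4.87 against 4.8 to 4.81, and Aspm in wild type unirradiated replicate 2, 8.07 against 7.92 to 7.93. Chance sets about 1 in 20 groups apart in this way, and 8 of the 80 groups tested were, against 4 expected by chance. Most of these 8 were the 18S controls of 1 extract, Oct-1 mutant unirradiated replicate 4. The groups are thus not independent, and the 8 show no general excess. The G2/M list differed between the genotypes in its irradiation effect, with a median of -0.1 on array A, and this call was absent with an estimated correlation (adjusted p = 0.975), with no filter (0.0788) and within the first number run (0.12).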

How the results depend on the processing

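The settings without Oct-1 mutant unirradiated replicate 4 with the block, and the list tests by number run, were chosen only after the data were seen. Counts stayed within 1.5 times with quantile normalization, no filter, no trend and array weights. With the replicate block they were 1653 (irradiation in wild type), 1938 (in the mutant), 1740 (genotype, unirradiated), 1632 (irradiated), 4040 (irradiation averaged) and 3769 (genotype averaged). With the number run block they were 1632, 1928, 1683, 1621, 3985 and 3712 in the same order. With the block within genotype, irradiation gave 1609, 1943 and 4043 (averaged). Without Oct-1 mutant unirradiated replicate 4 and with the block the counts were 1743, 1864, 1242, 1799, 3991 and 3359. A block takes the difference between runs out of the residual variance. Within the second number run irradiation gave 355, 357 and 1203 calls, from 2 arrays per group. Leaving out each extract gave 424–662 and 489–820 for irradiation in wild type and mutant, 380–569 and 382–610 for genotype in unirradiated and irradiated cells, and 1693–2231 and 1369–1667 for the averages. The difference of the irradiation effects gave 0–1. Of 70 list calls 18 remained with an estimated correlation, 62 with no filter, 64 and 61 within the first and second number run, and 65 without Oct-1 mutant unirradiated replicate 4. The G2/M call on the difference was lost with no filter (adjusted p = 0.0788). Immediate early genes in the irradiated mutant went to a median of 0 with the opposite direction of test within the second number run (adjusted p = 0.936), and the cause was not tested. Of 180 values of called named genes none reversed, but calls were lost for 18 and 29 within the first and second number run, 5 with no filter, 3 with array weights and 17 on leaving out 1 extract. Log2 offsets of 1 and 64 were not run, since the values are on a log scale already. Array medians were 3.67 to 3.78 on array B against 6.16 to 6.28 on array A. Little signal over background may hide small changes, which was not tested.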

Other observations

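The test of less signal far from the 3 prime end, the RNA degradation test, both tests of the sex of the cells and the place of named genes on chromosome 1 were chosen only after the results were seen. Between the number runs, Tfrc, the transferrin receptor, was lower in the second run by 3.24 on log2 scale, the topoisomerase Top2b by 2.58 and the enkephalin precursor Penk by 2.33 on array A, while Col1a1, a collagen chain, was higher by 1.37. In all, 6234 of 13582 probe sets differed between the runs on array A and 2134 of 13502 on array B. Of 38 G1/S genes 30 were lower in the second run (median -0.24, adjusted p = 0.019 with an estimated correlation), as were 26 of 41 G2/M genes (median -0.21, adjusted p = 0.0122 with an estimated correlation). Of 52 extracellular matrix genes 34 were higher (median 0.24, adjusted p = 0.166 with an estimated correlation).

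The arrays part by number run in every group. Quantile normalization left 96.7% of the first component's share or more, which argues against differences in the overall distribution of values between arrays as the cause. The arrays were already alike before it, with medians of 6.16 to 6.28 on array A and 3.67 to 3.78 on array B. How the authors summarised and scaled the values is not given, so their processing stays open. RNA degradation stays open: the Gapdh 3 prime minus 5 prime difference was 0.22 higher in the second run on both array types (exact p = 0.0015) and that of beta-actin was farthest from 0 at -0.02, under a rule written after these values were seen. Only 23.5% of 570 other probe sets followed a probe set of the same gene that was over 2-fold lower in the second run, which is consistent with less signal far from the 3 prime end. That hypothesis and its bounds were found and tested on the same data after probe sets of Tfrc and Top2b were looked at, probe set positions were not measured, and the 3 prime transferrin receptor control also fell by 1.47 on array A, so the cause stays open.

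The genotype differences may have causes other than the Oct-1 mutation. Probe sets on X or Y made up 4.35% of the calls, against 3.27% of those tested (odds ratio 1.38, Fisher exact p = 0.0179). Direct dosage of X and Y genes can account for these calls at most. Only 719 X or Y probe sets were tested against 1563 calls with a known chromosome. They could not have made up most of the calls, so this share is no test of that. In the 8 wild type arrays of type A, 1 Xist probe set was at 8.19 to 9.78 and Eif2s3y at 3 to 4.02. In the 8 mutant arrays they were at 3.16 to 3.29 and at 8.46 to 9.32. This is the pattern of female wild type and male mutant cells. Indirect effects of the sex of the cells stay open, since 0 of 16 arrays broke this link with genotype. Of the 100 genes nearest the mutated gene 17% were called against 10.2% of all genes (odds ratio 1.81, Fisher exact p = 0.0306), and for irradiation 9% against 12.3%. Gas5 was among these called genes, and Ifi202b was the 54th gene on its side. Chromosome 1 held 8% of the calls against 6.15% of the probe sets tested (Fisher exact p = 0.00221). It held 4.88% of the irradiation calls, a departure in the other direction (Fisher exact p = 0.0141). The near genes made up 1.36% of the called genes, but at most 7.97% was possible, so this share excludes nothing. Called genes lay next to a gene called the same way 1.66 times as often as in shuffled orders (1.69 without the 100 genes nearest the mutated gene, 1.18 for irradiation with all genes). Second probe sets followed 13 percentage points less often than for irradiation, 71.7% against 84.7% (Fisher exact p = 0.0638). These 60 and 85 probe set pairs came from only 30 and 41 genes, and some were counted in both orders. The test takes them as independent, which they are not. DNA of another strain, around the mutated gene or elsewhere, and sequence differences under the probes therefore stay open, and cells of both sexes in each genotype would part only the effect of sex from the rest.

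Genes changed by irradiation might also differ by genotype in the same direction. The probe sets called the same way in both averaged comparisons numbered 236, 2.4 times the 98.5 for independent lists, above the bound of 1.5 set beforehand. Those called in opposite directions, looked at only afterwards, were 1.46 times as many as for independent lists, and the effects correlated at 0.12 over probe sets on array A. Probe sets with strong signal are called more easily in both, which was not tested, so the hypothesis stays open.

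Exchanging group labels tested whether chance can be excluded. For irradiation in the mutant 1 of 35 splits, the real one, gave 724 calls or more (highest other 340, following the number run). This met the rule set beforehand. The splits exchange arrays across the runs, which differ, and the rule was not adjusted over the comparisons. It therefore does not exclude chance on its own. For irradiation in wild type 2 of 35 splits reached 625 (highest other 2417), for genotype in unirradiated cells 2 of 35 reached 585 (highest other 1322) and for genotype in irradiated cells 2 of 35 reached 565 (highest other 585), so chance was not excluded by this rule, which takes no account of the runs. In each of these 3 the other split followed the number run, all further splits gave at most 3 calls, and the counts with the number run block were 1632, 1683 and 1621. For the difference of the irradiation effects the real count was 0, which 35 of 35 splits reach by definition (highest other 3), so the splits test nothing there. For irradiation averaged 2 of 100 splits reached 2034 (highest other 2307, following the run in 1 genotype). For genotype averaged 1 of 100 reached 1696 (highest other 779). Both averaged comparisons met the same rule, with the same limit. The origin of the replicates is not given, so for genotype the splits cannot exclude a chance difference between the embryos or cultures they came from.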
